A study of Mus musculus with 6 samples.

How the data were processed

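Gene expression was measured by bulk RNA sequencing in MDA-F471, a mouse lung adenocarcinoma cell line whose genotype the labels give as Gprc5a-/- and which, per the series title, carries mutant Kras. The labels put 6 libraries in 2 groups of 3. The parental cells were kept in DMEM/F-12 medium with 10% fetal bovine serum, and the other group came from spheres, which the labels call cancer stem cells, raised in a sphere formation assay from cell suspensions mixed in equal parts with growth factor-reduced Matrigel and medium. Per the labels' protocols, 500 ng of total RNA was depleted of ribosomal RNA, made into stranded paired-end libraries of 101 bp reads and sequenced on a NovaSeq instrument. The labels describe the 3 libraries of each group as biological replicates and do not say how the cultures were split or when they were harvested, so the p-values measure the spread between these cultures of 1 line.

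The deposited table held 1 whole-number count per library for each of 36780 RefSeq transcripts of 24532 genes. The submitters' processing notes name FastQC, Trimmomatic, HISAT2, StringTie and DESeq2 and the mouse build mm10, with no versions, roles or order, and how strand was used in counting is not given in the sources used here. The authors' deposited values were treated as estimated counts, because transcripts of 1 gene shared its reads in shifting parts, and they were whole as deposited, so no further rounding was needed. They had no scaling for depth. A count per gene had been assumed before the data were examined, so the transcripts were summed by NCBI gene number, which removes most of the uncertainty about which isoform a read came from. Reads shared with a near-identical gene can still be placed on the wrong copy. No row lacked a gene, and the table had no mitochondrially encoded gene. Column names carried the line's name alone for the parental cells and the same name with the suffix G1 for the spheres. The labels do not print that suffix, so it was read as the sphere group by elimination, and every direction given here would turn if that reading were wrong.

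Gene numbers were matched to a RefSeq annotation of GRCm38, the assembly that mm10 denotes, and 24462 of the 24532 were found. It gave the coordinates, which are 1-based, and the gene types. The table's symbols were used, except that 27 symbols that had been turned into dates were restored through the gene number.

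Library totals were 33747534, 37355789 and 29423695 counts in the parental libraries and 25269337, 29682624 and 34747775 in the sphere libraries. A floor of 3 counts corresponds to a counts-per-million value (CPM) between 0.08 and 0.119 in 1 library, and to 0.0294 over the parental and 0.034 over the sphere group. A fold against a group with no count was computed against the floor over the whole group and is a lower bound. With 1 to 3 counts in a group, the ratio is given with an exact 95% interval. Floors and intervals cover counting error only, since the libraries had no molecular identifiers. No 2 replicates of the same group agreed within sampling noise. The chi-square per degree of freedom between replicates was 10.45 to 15.72 in the parental group and 27.3 to 58.74 in the sphere group, over genes with a summed count of at least 20 in the pair.

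Genes were filtered with filterByExpr and scaled by TMM, and spheres were compared with parental cells by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the group as the sole term. P-values were adjusted by the Benjamini-Hochberg method over the 12656 genes tested, at a threshold of 0.05. Levels are TMM-scaled CPM, as mean ± SD of 3 libraries, and log2 fold changes carry the standard error that the test implies. Before the data were examined, 40 gene lists were fixed: stem cell markers, epithelial and mesenchymal genes, alveolar type 2, alveolar type 1 and airway genes, proliferation, DNA replication, replication histones, cholesterol and fatty acid synthesis, hypoxia and glycolysis, interferon response, antigen presentation, inflammatory NF-kB targets, epithelial host defence, unfolded protein response, integrated stress response, NRF2 targets, p53 targets, RAS-ERK, YAP-TEAD, WNT, NOTCH and TGF-beta and BMP targets, fibrillar matrix, basement membrane, matrix proteases, integrins, mitochondrially encoded and nuclear respiratory chain genes, ribosomal proteins, autophagy and lysosome, drug transport and metabolism, immediate early genes, and markers of fibroblasts, endothelium, leukocytes, the Matrigel tumour and neuroendocrine cells. Lists with at least 3 tested genes, 38 in all, entered camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists. A gene with almost no count in 1 group passed the filter through the other group alone, so it could only be called higher there. Camera with an estimated correlation and fry were alternatives. Where a list's median in sphere replicate 1 is set against the other spheres, it is a median of differences over the list's genes. Each difference is the gene's log2 CPM in that library minus its mean log2 CPM in sphere replicates 2 and 3.

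Genes were named by a rule fixed before the data were examined: Gprc5a and Kras, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM, a named symbol and groups that did not overlap, up to 2 largest rises and 2 largest falls of each list (or its most abundant gene where none was called), and the 5 most abundant genes of each group. Other genes are marked as chosen after their values were seen.

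The procedure was tested on simulated counts of 12267 genes, drawn mostly from the parental means, with these libraries' depths and 1 dispersion per gene for both groups. Known changes were set in 63 genes at 1.5-fold, 64 at 2-fold and 62 at 4-fold, and 12078 were left unchanged. The quasi-likelihood test called 39.7% of 1.5-fold, 75% of 2-fold and 87.1% of 4-fold changes with 7 false calls, 5.22% of all calls. DESeq2 1.42.0 had 17.98% false calls and limma voom 2.27%. The real comparison called 59.6% of genes, and its biological coefficient of variation was 0.202 in spheres against 0.088 in parental cells. The simulated rates do not cover such wide change or unequal spread. In a simulation with 1 changed list among 40, with genes drawn independently of one another, camera called that list and no other, both with the preset and with an estimated correlation.

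Alternatives were other scalings (DESeq2 size factors, upper-quartile factors and library totals), no filter, a filter of 1 CPM in 3 libraries, the DESeq2 Wald test, limma voom, the replicate number as a block, each library left out in turn, a test against a 2-fold change (glmTreat) and protein-coding genes alone. After the data were seen, a test per transcript and a test without genes that had an exact 0 in 1 library were added, and the gastric and squamous lists, which were written at that stage, were tested without members of the fixed lists and without each library in turn. A planned test on TPM or FPKM values was not run, since the table used here held counts. No column of the table was left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.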

Results

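Whole-transcriptome profiles were compared between MDA-F471 mouse lung adenocarcinoma cells in standard serum-containing culture (parental cells, n = 3) and the spheres derived from them in Matrigel, labelled as cancer stem cells (n = 3). Each library held between 25269337 and 37355789 counts. Between 13893 and 14104 genes had a count in the parental libraries and between 14354 and 14432 in the sphere libraries. The comparison asks how gene expression differs between the line in serum culture and the spheres. Culture in Matrigel went with the group. Any difference in medium supplements or harvest time, which the labels do not give for the spheres, would go with it too. The effects of these conditions cannot be told apart from traits of the sphere-forming cells.

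Gprc5a (chr6:135065662-135084708, mm10), a lung tumour suppressor gene for which the line is labelled -/-, had a low level in all libraries, above the floor of 3 counts, with 54, 50 and 43 counts in parental replicates 1 to 3 and 74, 64 and 49 in sphere replicates 1 to 3. These correspond to 1.44 ± 0.13 and 2.21 ± 0.80 CPM (SD, n = 3 each), a difference that did not pass the test (edgeR adjusted p = 0.169). The counts give no position within the gene and the labels do not name the part deleted, so they do not check the genotype. Kras (chr6:145216699-145250231) was 1.27-fold lower in spheres, at 49.9 ± 3.8 against 63.7 ± 4.8 CPM (log2 fold change -0.35 ± 0.09 SE, adjusted p = 0.00917).

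The spheres differed from the parental cells across much of the transcriptome measured. Clca1, Muc5b, Cxcl15 and Aldh1a1 were among the genes higher in spheres, and Krt14, Col7a1 and Ret among those lower. As lists, inflammatory NF-kB targets and NRF2 targets were called higher and proliferation, DNA replication and histone genes lower by camera with a preset correlation. None of these 5 calls held with an estimated correlation (adjusted p = 0.149 for DNA replication and adjusted p = 0.647 for each of the others). Of 12656 genes tested, 7542 (59.6%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3904 higher and 3638 lower in spheres. Changes of more than 2-fold in the estimate leaned upward, with 1705 called genes higher and 884 lower, and against a threshold of 2-fold the test called 1156 higher and 422 lower. No parental library had a count for 152 of the genes called higher, and no sphere library for 20 of those called lower. The groups did not overlap for 8683 genes (68.6%), where chance gives 10%. The first principal component held 85% of the variance and separated the groups. Spheres varied more between replicates, with a biological coefficient of variation of 0.202 against 0.088 in parental cells, and sphere replicate 1 stood apart on the second component (6.2% of the variance), at 41.2 against -21.3 and -23.8 for sphere replicates 2 and 3.

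The genes with the largest rises were nearly all unexpressed in the parental cells. Clca1 (chr3:145004537-145032776), a secreted product of goblet cells, had no count in the parental libraries and 514 ± 268 CPM in spheres, at least 16600-fold higher. Itih2 (chr2:10094591-10130683), a heavy chain of the inter-alpha-trypsin inhibitors, reached 339 ± 15 CPM and was at least 11600-fold higher. Cxcl15 (chr5:90794534-90803067), a chemokine of lung epithelium, reached 198 ± 12 CPM and was at least 6710-fold higher. Muc5b (chr7:141839072-141873085), a gel-forming airway mucin, rose to 261 ± 109 CPM from 3 parental counts, all in parental replicate 3, a ratio of 8640 with an exact 95% interval of 2950 to 41900. The ratio for Muc5b was 5740 (1960 to 27800) without parental replicate 1 and 5430 (1860 to 26300) without parental replicate 2, and without parental replicate 3, which leaves no parental count, it was at least 6100-fold higher. Sptssb, a subunit of serine palmitoyltransferase, was at least 2820-fold higher, and Sftpd (chr14:41172212-41185198), surfactant protein D, at least 2070-fold. For Gkn2, a gastrokine of the stomach lining, the bound was 1570-fold, for Oit1 it was 1250-fold and for Eps8l3 it was 1150-fold. The adjusted p of these genes lay between 2.48e-07 (Itih2) and 0.000192 (Sftpd). Olfm4 (chr14:80000302-80023141), a marker of intestinal crypt cells, had an adjusted p of 0.00414 and 173, 21.0 and 14.9 CPM in sphere replicates 1 to 3. It was at least 2070-fold higher over all spheres and at least 605-fold without sphere replicate 1, and it was not called by limma voom.

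Among the largest falls were secreted factors, basal epithelial genes and a growth factor receptor. Il24 (chr1:130882074-130887411), a cytokine, fell 49.2-fold from 33.8 ± 1.5 to 0.69 ± 0.40 CPM (log2 fold change -5.62 ± 0.32 SE, adjusted p = 5.21e-06). Inhbb, the activin beta B subunit, fell 35.3-fold from 110 ± 3.9 to 3.17 ± 1.5 CPM. Krt14 (chr11:100203162-100207510), a basal cell keratin, fell 23.9-fold from 166 ± 5.5 to 6.92 ± 2.0 CPM. Col7a1 (chr9:108953745-108984875), the collagen of anchoring fibrils, fell 18.2-fold from 88.0 ± 5.3 to 4.84 ± 0.59 CPM, and the receptor tyrosine kinase gene Ret (chr6:118151748-118197744) 16.1-fold from 115 ± 6.3 to 7.19 ± 1.7 CPM. The others were Podnl1 (23.7-fold), the water channel gene Aqp8 (18.6-fold), Serpinb2, which encodes plasminogen activator inhibitor 2 (16.9-fold), S100a7a (15.8-fold) and Sh2d1b1 (14.2-fold). All 10 had an edgeR adjusted p of 9.33e-06 or below.

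**Figure D1:**
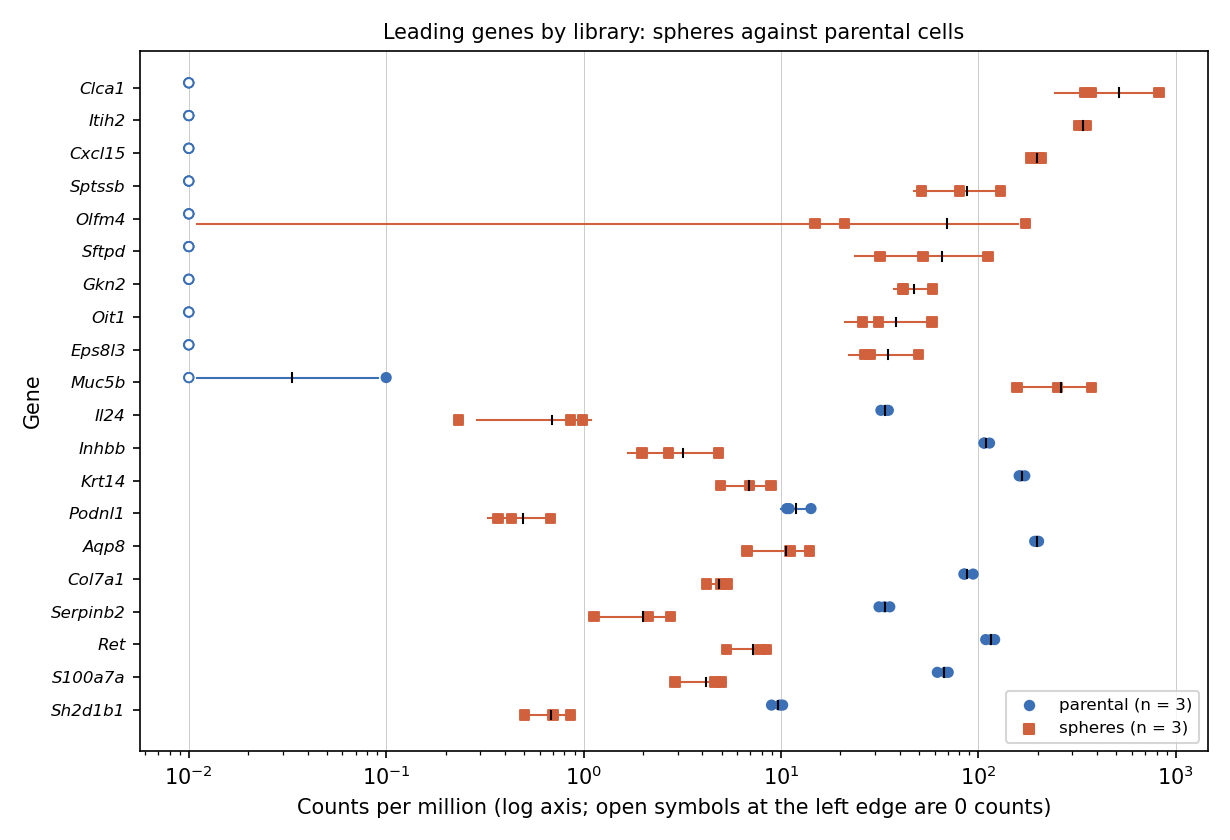
Scaled CPM (log axis) of the 10 largest rises and 10 largest falls, with 1 symbol per library, circles for parental cells and squares for spheres (n = 3 each). Open circles are libraries with no count, black ticks are means and bars are SD, which end at the left edge where they would pass below 0. The groups do not overlap for any of the 20 genes, and Clca1, Itih2 and Cxcl15 had no parental count against means of 514, 339 and 198 in spheres.

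Alveolar type 2 genes were called higher as a list, and airway and alveolar type 1 genes were not called by camera. Of the 16 alveolar type 2 genes fixed, 9 were abundant enough to test, and 7 of these rose and 2 fell. Cxcl15, Sftpd and Hc (the last chosen after its values were seen) had no parental count. These 3 were tested only through the spheres and could only rise, so the tally leans upward by design. Cxcl15 and Sftpd led the rises, while Lpcat1, a surfactant lipid enzyme, fell 2.87-fold and the transcription factor gene Etv5 fell 1.67-fold. The list was called higher by camera (adjusted p = 4.93e-07, and adjusted p = 0.149 with an estimated correlation), and it was not called with limma voom (adjusted p = 0.0693). Sftpc, Sftpa1 and Nkx2-1, chosen after their values were seen, had no count in any of the 6 libraries. Of the 16 airway genes fixed, 11 were abundant enough to test. Among these, 7 rose, Krt14 fell and 3 did not pass the test. Muc5b and Muc5ac (0 to 25.8 ± 8.7 CPM, at least 881-fold) were among the rises. For 3 of the 7 there was no parental count, so these 3 could only rise. The airway list did not pass in the main test (adjusted p = 0.0613, and adjusted p = 0.352 with an estimated correlation). It passed in 10 of the 17 alternatives, with upper-quartile factors for example (adjusted p = 0.0374). Alveolar type 1 genes went both ways, with 5 of 14 higher and 4 lower. Clic5 had a mean of 2.48 ± 2.65 CPM against 0.084 in parental cells, 27.1-fold higher, and 10.5-fold without sphere replicate 1 or 69.1-fold without parental replicate 2. Rtkn2 fell 5.31-fold. The alveolar type 1 list was not called (adjusted p = 0.542), and its median of 0.33 was positive where the test pointed down. Genes of these lists lay above the other spheres in sphere replicate 1 by a median of 0.48 (alveolar type 2), 0.91 (airway) and 0.95 (alveolar type 1) on the log2 scale.

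Genes of the epithelial list, which holds junction, keratin, protease and transcription factor genes among others, were mostly higher. Of 22 tested, 15 rose, 1 fell and 6 did not pass the test, and the list was called higher (camera adjusted p = 0.00129, and adjusted p = 0.754 with an estimated correlation). Muc1, a membrane mucin, rose 6.33-fold from 33.7 ± 1.0 to 213 ± 60 CPM, and the tight junction gene Ocln rose 5.01-fold from 45.6 ± 1.2 to 228 ± 30 CPM. Krt7, a keratin of simple epithelia, fell 1.78-fold from 1790 ± 64 to 1005 ± 44 CPM. The list's median log2 fold change was 0.75, and in sphere replicate 1 its median lay 0.32 above the other spheres. Mesenchymal genes were not called as a list (adjusted p = 0.882), with 3 of 13 higher and 5 lower. Fibronectin (Fn1) rose 3.32-fold from 409 ± 46 to 1357 ± 277 CPM and the integrin gene Itgb3 rose 3.28-fold. Cdh2 (N-cadherin) was low throughout, at 3.39 ± 0.51 and 0.34 ± 0.42 CPM, a fall of 10.1-fold (36.5-fold without sphere replicate 2 and 6.50-fold without sphere replicate 3).

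Stem cell markers, the class that the label of the spheres refers to, were mixed. Of the 24 genes fixed, 18 were abundant enough to test, and 10 of these rose and 6 fell. Sox2, Nanog, Pou5f1, Prom1, Kit and Cxcr4 were too low to test. Nanog and Pou5f1, chosen after their values were seen, had no count in any of the 6 libraries. The aldehyde dehydrogenase genes Aldh1a1 (chr19:20601982-20643462), which rose 56.9-fold from 7.64 ± 0.81 to 434 ± 44 CPM (adjusted p = 1.84e-07), and Aldh1a3 (chr7:66390893-66427477), which rose 64.7-fold from 0.158 ± 0.023 to 10.4 ± 2.6 CPM, led the rises. Ncam1 fell 9.20-fold from 70.6 ± 5.9 to 7.76 ± 3.7 CPM and Ly6a (Sca-1) fell 3.95-fold from 292 ± 9.4 to 74.1 ± 18 CPM. The list was called higher (camera adjusted p = 0.0214, and adjusted p = 0.682 with an estimated correlation). Without sphere replicate 1 it was not called (adjusted p = 0.14), nor with limma voom (adjusted p = 0.268), and in that library its median lay 0.28 above the other spheres on the log2 scale.

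Most tested genes of the inflammatory, host defence, interferon and antigen presentation lists were higher in spheres. Of 20 inflammatory NF-kB targets, 17 rose and none fell (camera adjusted p = 3.01e-10, and adjusted p = 0.647 with an estimated correlation). The neutrophil chemokine Cxcl2 (chr5:90903899-90905938) rose from 0.170 ± 0.171 to 70.9 ± 40 CPM, 394-fold (861-fold without parental replicate 2). Of the 17 secreted host defence genes fixed, 8 were abundant enough to test. Among these 8, 7 rose and none fell (adjusted p = 0.0134, 0.075 with limma voom, and adjusted p = 0.706 with an estimated correlation). Complement C3 (chr17:57203967-57228136) rose 383-fold from 0.446 ± 0.102 to 174 ± 100 CPM. Lcn2, an iron-binding defence protein, had 72.5, 2.27 and 3.72 CPM in sphere replicates 1 to 3 against 0.073 ± 0.085 in parental cells. Its rise of 357-fold became 41.1-fold without sphere replicate 1 and 820-fold without parental replicate 3, and limma voom did not call it. Of the 27 interferon-stimulated genes fixed, 18 were abundant enough to test, and Ifit1, Ifit3, Oas2 and Rsad2 were among those that were not. Among the 18, 11 rose and none fell (adjusted p = 0.00177, and adjusted p = 0.647 with an estimated correlation). The other 7, Stat1 among them, did not pass the test. Cxcl10 was 288-fold higher at 94.5 ± 12 against 0.34 ± 0.17 CPM and Mx2 at least 98.1-fold higher. Of 14 genes of antigen presentation on MHC class I, 9 rose and 1 fell (adjusted p = 0.0159, and adjusted p = 0.706 with an estimated correlation). Tapbp (tapasin) rose 5.37-fold from 30.4 ± 0.87 to 163 ± 6.2 CPM. The member that fell was Nlrc5, a transactivator of class I genes, from 0.70 ± 0.11 to 0.12 ± 0.16 CPM, and its call was lost without any 1 parental replicate or sphere replicate 3 (adjusted p = 0.0713 to 0.0973). Without sphere replicate 2 the fall was 18.8-fold against 5.52-fold. Genes of these lists lay above the other spheres in sphere replicate 1, on the log2 scale. The median difference was 0.84 (inflammatory), 1.57 (host defence), 0.57 (interferon) and 0.26 (antigen presentation). The chemokine, Mx and MHC genes have close paralogs, so the split of reads among them is uncertain.

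Proliferation genes were lower in spheres without an exception in the list. All 23 mitotic and proliferation genes fell (camera adjusted p = 3.01e-10, and adjusted p = 0.647 with an estimated correlation), by a median of -0.93 on the log2 scale. Aurka, a mitotic kinase gene (chr2:172356190-172370570), fell 2.62-fold from 119 ± 3.3 to 45.6 ± 4.1 CPM and Plk1 fell 2.31-fold from 62.3 ± 2.2 to 27.0 ± 0.81 CPM. Of 24 DNA replication genes, 23 fell and none rose (adjusted p = 2.02e-07, and adjusted p = 0.149 with an estimated correlation), among them Tk1, 2.40-fold from 175 ± 2.5 to 72.9 ± 4.0 CPM, and Cdc45, 2.21-fold. All 19 replication-dependent histone genes fell (adjusted p = 1.78e-07, and adjusted p = 0.647 with an estimated correlation), with a median of -0.78. Hist1h2bb fell 2.34-fold from 600.0 ± 14 to 256 ± 21 CPM. Histone genes are near-identical copies of one another, so the values of single members are uncertain. In sphere replicate 1 the medians of the proliferation and histone lists lay 0.19 and 0.22 above the other spheres on the log2 scale, while that of DNA replication differed by -0.04. The G1 cyclin gene Ccnd1, of the RAS-ERK and WNT lists, fell 2.80-fold from 1181 ± 20 to 422 ± 36 CPM.

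The NRF2, drug metabolism and autophagy lists were called higher, each with members that fell. Of 21 NRF2 targets, 16 rose, 2 fell and 3 did not pass the test (camera adjusted p = 3.01e-10, and adjusted p = 0.647 with an estimated correlation). Gsta4 (chr9:78191966-78209349) rose 20.6-fold from 51.8 ± 1.7 to 1069 ± 42 CPM (adjusted p = 6.73e-08) and Gstm1 (chr3:108012250-108017973) 24.0-fold from 39.8 ± 3.4 to 956 ± 140 CPM. Both encode glutathione transferases with close paralogs. The members that fell were G6pdx (1.63-fold) and Taldo1 (1.32-fold), enzymes of the pentose phosphate pathway. Sphere replicate 1 lay below the other spheres for this list, by a median of -0.28 on the log2 scale. Of 16 drug transport and metabolism genes, 10 rose and 4 fell (adjusted p = 0.000162, and adjusted p = 0.149 with an estimated correlation). Sult1a1, a sulfotransferase gene, was at least 105-fold higher, and the glucuronosyltransferase gene Ugt1a7c, whose exons are shared with its neighbours, at least 76.9-fold. The efflux pump gene Abcb1b fell 2.13-fold from 294 ± 5.9 to 138 ± 22 CPM. In sphere replicate 1 the median of this list lay 0.23 above the other spheres. Of 21 autophagy and lysosome genes, 17 rose and 3 fell (adjusted p = 0.0214, and adjusted p = 0.647 with an estimated correlation). The autophagy receptor gene Sqstm1 rose 4.07-fold from 240.1 ± 2.1 to 976 ± 178 CPM, while Atg9b fell 6.96-fold and the protease gene Ctsl 2.76-fold. The autophagy list was not called without sphere replicate 3 (adjusted p = 0.0686).

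**Figure D2:**
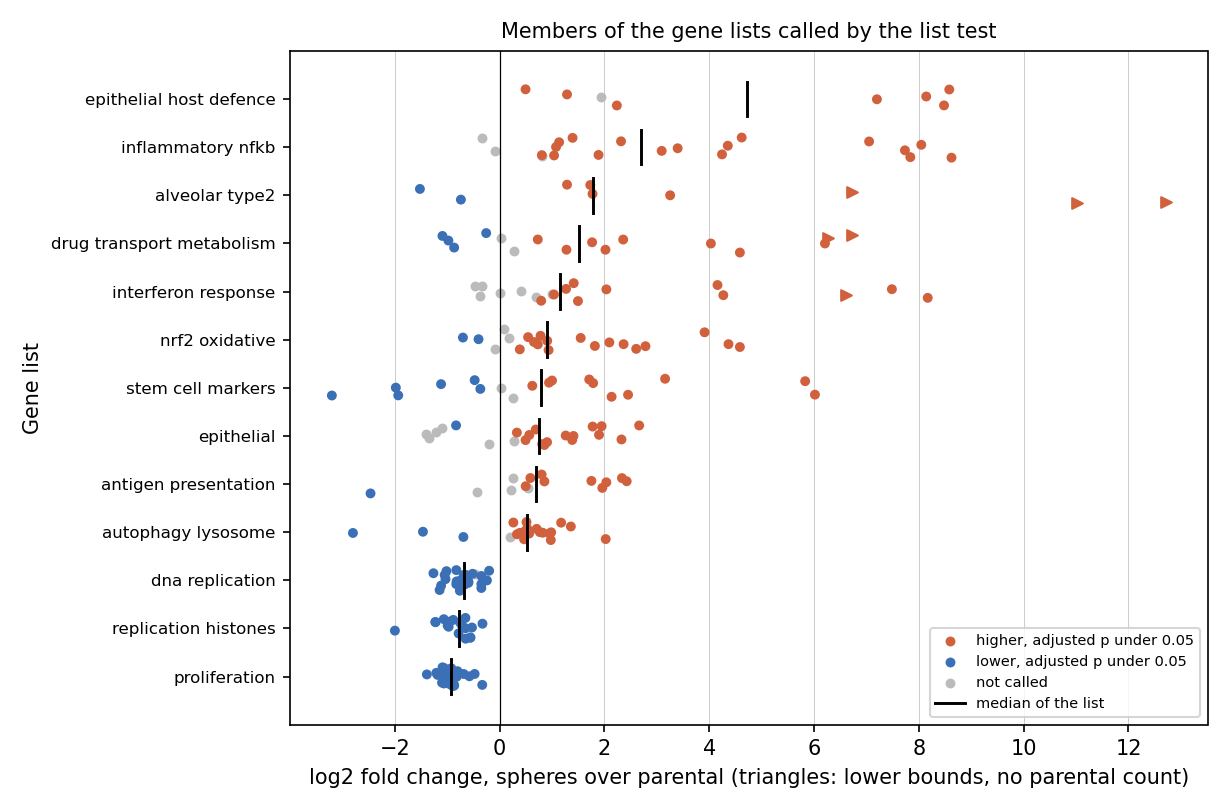
Log2 fold change of each tested member (1 symbol per gene) of the 13 lists called by camera, spheres over parental cells, with medians as black lines. Triangles mark lower bounds for genes with no parental count, and grey symbols did not pass the test. All members of the proliferation list (median -0.93) and of the histone list (median -0.78) lie below 0, while the inflammatory list has a median of 2.70.

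Immediate early genes rose in 13 of 20 cases, with none lower, yet the list was not called (camera adjusted p = 0.0793, and adjusted p = 0.924 with an estimated correlation). It passed in 6 of the 17 alternatives, with an adjusted p of 0.000124 without sphere replicate 2. Fos (chr12:85473901-85477270) had 1230, 199 and 526 CPM in sphere replicates 1 to 3 against 38.8 ± 5.9 in parental cells, and its 16.8-fold rise was 9.32-fold without sphere replicate 1. The list's genes lay above the other spheres in sphere replicate 1 by a median of 1.21 on the log2 scale. RAS-ERK targets were balanced, with 6 of 20 higher and 6 lower (adjusted p = 0.512). YAP-TEAD targets were mostly lower, with 10 of 18 lower and 3 higher, short of a call (adjusted p = 0.205). Ankrd1 fell 5.83-fold from 567 ± 13 to 97.5 ± 61 CPM and Ctgf 5.48-fold from 308 ± 9.4 to 56.4 ± 35 CPM, and without sphere replicate 1 the fall of Ctgf was 8.40-fold and the log2 fold change of Ankrd1 was -3.17. Without that library the YAP-TEAD list (adjusted p = 0.00904) and the RAS-ERK list (adjusted p = 0.0326) were called lower. In it, their medians lay 0.42 and 0.92 above the other spheres on the log2 scale.

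Other signalling and stress lists moved both ways and were not called by camera. The integrated stress response list had 4 of 19 genes higher and 9 lower (adjusted p = 0.224): the cystine transporter gene Slc7a11 rose 6.88-fold from 47.6 ± 2.4 to 328 ± 138 CPM, and Mthfd2, of mitochondrial folate metabolism, fell 3.08-fold. Of 19 unfolded protein response genes 7 rose and 3 fell (adjusted p = 0.512), led by Herpud1 at 5.52-fold. Of 17 p53 targets 4 rose and 7 fell (adjusted p = 0.338), with Trp53inp1 4.05-fold higher and Phlda3 2.26-fold lower. WNT targets had 3 of 11 higher and 4 lower (adjusted p = 0.489). The stem cell receptor gene Lgr5 rose 8.92-fold from 0.353 ± 0.287 to 3.24 ± 0.76 CPM (17.0-fold without parental replicate 2) and Apcdd1 fell 3.84-fold. NOTCH genes had 3 of 11 higher and 2 lower (adjusted p = 0.883), with Notch2 2.25-fold higher and Nrarp 2.18-fold lower. TGF-beta and BMP targets had 7 of 15 higher and 3 lower (adjusted p = 0.512, and 0.0374 without sphere replicate 3), with Bmp2 10.9-fold higher and Pmepa1 2.51-fold lower. Median, mean and test differed in sign for the RAS-ERK, WNT and NOTCH lists. In sphere replicate 1 the medians differed from the other spheres by -0.40 (integrated stress response), 0.17 (unfolded protein response), 0.29 (WNT) and 0.68 (TGF-beta and BMP) on the log2 scale.

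Metabolic lists and ribosomal proteins were not called by camera. Of 23 cholesterol synthesis genes, 1 rose and 3 fell (adjusted p = 0.512), with Srebf2 1.49-fold higher and Mvk 1.59-fold lower, and sphere replicate 1 lay below the other spheres by a median of -0.61 on the log2 scale. Fatty acid synthesis genes went both ways, 6 of 18 higher and 5 lower (adjusted p = 0.728), with Acacb 9.26-fold higher and Elovl6 1.94-fold lower, and in sphere replicate 1 their median lay below the other spheres, by -0.26. Hypoxia and glycolysis genes had 12 of 27 higher and 3 lower (adjusted p = 0.175), among them Egln3, 4.24-fold higher, and Eno1, 1.47-fold lower, and their median was 0.11 higher in sphere replicate 1. Nuclear respiratory chain genes had 7 of 22 lower and none higher (adjusted p = 0.34), led by Uqcrc1 at 1.44-fold, and their median differed by -0.13 in sphere replicate 1. Ribosomal protein genes had 2 of 24 higher and 5 lower (adjusted p = 0.512), with Rpl23 1.18-fold higher and Rps2 1.45-fold lower. The 13 mitochondrially encoded genes were not in the table.

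Matrix and integrin genes went both ways. Basement membrane genes had 6 of 15 higher and 6 lower (adjusted p = 0.882), with Lamb2 3.97-fold higher at 235 ± 23 CPM and Col18a1 2.26-fold lower at 404 ± 34 CPM. Fibrillar matrix genes had 5 of 11 higher and 4 lower (adjusted p = 0.985), Col5a1 falling 2.64-fold. Dcn and Col12a1, near the floor in parental cells, rose to 0.70 ± 0.18 and 1.87 ± 0.81 CPM. Matrix proteases and their inhibitors had 7 of 15 higher and 5 lower (adjusted p = 0.985), the collagenase gene Mmp13 rising 17.6-fold from 5.07 ± 0.44 to 89.5 ± 35 CPM and Timp1 falling 3.06-fold. Among 12 integrin genes 6 rose and 4 fell (adjusted p = 0.263). Itga3 fell 1.87-fold from 1042 ± 38 to 556 ± 21 CPM. In sphere replicate 1 the medians of the fibrillar matrix and integrin lists lay 0.38 and 0.20 above the other spheres on the log2 scale.

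Markers of other cell types were few and not called as lists by camera. Of fibroblast and mesothelial markers 1 of 4 rose and 3 fell (adjusted p = 0.263), the mesothelial gene Msln falling 2.88-fold from 853 ± 22 to 296 ± 16 CPM. Among endothelial markers 1 of 3 rose and 1 fell (adjusted p = 0.883), with Flt1 1.55-fold higher. Of 3 leukocyte and macrophage markers 1 fell and none rose (adjusted p = 0.485), Mrc1 falling 2.80-fold from 241 ± 9.0 to 86.0 ± 21 CPM. Genes of the tumour that Matrigel is made from went both ways, 4 of 9 higher and 4 lower (adjusted p = 0.588). Stra6, a vitamin A transporter gene, was at least 167-fold higher, and Dab2 fell 6.02-fold. Median and mean differed in sign for the fibroblast list. Neuroendocrine markers had 2 tested genes, too few for the list test, of which Uchl1 fell, at least 16.1-fold lower.

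Adjusted over the list alone, the counts of higher and lower genes were the same as over all genes for 32 lists. They differed for 7: epithelial (15 higher, 3 lower), alveolar type 1 (7 and 4), cholesterol synthesis (1 and 2), YAP-TEAD (3 and 11), ribosomal proteins (1 and 5), immediate early (14 and 0) and Matrigel tumour genes (4 and 5). In all, camera called 10 lists higher and 3 lower. None of the 13 calls held with an estimated correlation, where 3 lists had an unadjusted p under 0.05, while fry, which tests whether a list's genes move one way on balance, called 19. These were the 13 lists and 6 others, with the adjusted p from fry: hypoxia and glycolysis (0.00559, higher), airway (0.0128, higher), integrins (0.0128, higher), unfolded protein response (0.0418, higher), p53 targets (0.0252, lower) and fibroblast markers (0.000849, lower). Fry tests a list by itself, whereas camera sets it against all other genes. With 59.6% of genes called, a list passes fry more easily, so its count and that of camera answer different questions.

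The most abundant transcripts shifted modestly. Rn45s, the ribosomal RNA precursor that escapes depletion, made up 1.37 to 1.84% of counts in parental libraries and 1.88 to 2.65% in spheres, and non-coding genes together 3.74 to 4.19% and 4.90 to 5.88%. Rn45s was called 1.41-fold higher (adjusted p = 0.0235), but not without parental replicate 1 (adjusted p = 0.0657), parental replicate 3 (0.0831) or sphere replicate 3 (0.0521). Rpph1, the RNA of ribonuclease P, rose 1.70-fold to 12552 ± 1140 CPM. Actb fell 1.54-fold from 11380 ± 227 to 7411 ± 259 CPM and Ahnak 1.44-fold. Eef1a1 (13375 ± 337 and 12872 ± 1116 CPM, adjusted p = 0.518) and Rmrp (9643 ± 270 and 8848 ± 1140 CPM, adjusted p = 0.277) did not pass the test.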

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

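The count of changed genes moved by more than 1.5 times under 1 alternative. A test against a 2-fold change (glmTreat) called 1578 genes, 1156 higher and 422 lower, because it demands a larger effect. With each library left out in turn, edgeR called 6334 to 7947 genes, 3384 to 4042 of them higher and 2950 to 3905 lower, and between 82.7% and 95.8% of the main calls remained, with none reversed. Without sphere replicate 1, the library that stood apart, 7947 genes were called. Other scalings, filters, DESeq2, limma voom and protein-coding genes alone gave 7287 to 7679 calls, and the share of calls that were higher lay between 46.6% (upper-quartile factors) and 52.3%. Same-numbered libraries did not deviate together (r across genes -0.041, -0.039 and 0.009), so the numbers were not taken to pair the samples. A replicate block gave 6826 calls, 3517 higher and 3309 lower. It called the airway (adjusted p = 0.000299) and immediate early (0.0286) lists and not the autophagy list (0.072). Of the alternatives chosen after seeing the data, the test per transcript called 5767 genes, and the test without 3 genes that had an exact 0 in 1 library beside at least 5 CPM in the rest of its group (Acat3, Gm12070 and Dpm1-adnp, chosen after their values were seen) called 7547. The count of called lists was 13 in the main test and between 11 and 19 elsewhere, except that an estimated correlation called 0. For the 13 lists that estimate ran from -0.006 to 0.618 against the preset 0.01. For the drug transport and metabolism list it was -0.006, below the preset, yet the unadjusted camera p rose from 2.98e-05 to 0.011. A higher correlation therefore does not account for the loss of that call. With an estimated correlation, camera also refers its statistic to the few residual degrees of freedom of the 6 libraries. That raises p by itself, for each list. How much of the loss of the other calls came from it was not measured. Of 148 named genes, 145 were called in the main test. Of these, 92 kept their direction and call under each alternative run, 53 lost the call under at least 1 (most under glmTreat, 10 with a library left out) and none reversed. The other 3 (Gprc5a, Eef1a1 and Rmrp) were not called under any alternative run. Without sphere replicate 1, the fold or bound of 14 named genes moved by more than 1.5 times. The planned test on TPM or FPKM values was not run. Depth limits genes near the floor of 3 counts over a group, where bounds and exact intervals stand in place of folds.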

Other observations

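The tests on the gastric list, the squamous list, the Matrigel and lung tissue markers and the early-response genes were chosen after the results were seen, and the genes named here were chosen after their values were seen, except where the report names them. The tests on other splits, transcript length, overlapping genes and depth were set before their results were seen.

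Most tested gastric and intestinal epithelial genes were higher in spheres. Because Gkn2, Olfm4 and Clca1 stood among the largest rises, a list of 44 other gastric and gut identity genes was written with the leading genes left out. The lists fixed earlier hold Gata6 and Aqp5 of its tested members. Of the 44, 28 passed the filter on low counts, and 23 of these rose and 1 fell (24 and 1 adjusted over the list alone). Camera called the list higher (adjusted p = 1.85e-14 over this list and the next, and adjusted p = 0.0737 with an estimated correlation). Members with no parental count (Tff3 and Tm4sf5) or 2 parental counts (Hnf1a, Capn8 and Pdx1) were tested only through the spheres. The same held for Phgr1, Lgals2, Tff1 and Fabp2, with 6, 8, 14 and 15 parental counts. All of these members are among the 23 that rose. They could only rise, so the tally leans upward by design. Without Gata6 and Aqp5, 22 of 26 rose and none fell (adjusted p = 4.24e-16, and adjusted p = 0.0768 with an estimated correlation). In sphere replicate 1 the list's median lay 0.62 above the other spheres on the log2 scale. Without that library 24 of 29 rose and 1 fell (adjusted p = 5.27e-17, and adjusted p = 0.00986 with an estimated correlation). The other 5 libraries, left out in turn, gave an adjusted p between 9.65e-16 and 3.36e-14 with the preset correlation, and with an estimated correlation the list was not called in any of these 5 (adjusted p = 0.0997 to 0.111). The transcription factor gene Hnf4a (chr2:163506857-163572907) rose from 7.75 ± 0.39 to 304 ± 23 CPM (log2 fold change 5.29 ± 0.09 SE, edgeR adjusted p = 8.58e-08), and the gut lectin gene Lgals4 from 1.25 ± 0.25 to 308 ± 90 CPM. Foxa3 rose from 0.983 ± 0.186 to 23.2 ± 6.9 CPM and Cldn2 from 3.97 ± 1.11 to 87.4 ± 17 CPM, while Tff3 was at least 284-fold higher. Aqp5 fell from 105 ± 3.9 to 49.8 ± 3.8 CPM. Members also counted in parental cells, such as Hnf4a, Foxa1 and Tspan8, rose, as the hypothesis of a gastric and intestinal programme in the spheres holds. Hnf1b, Psca, Mal and Fabp1 were not called, and neither group had an Nkx2-1 count. Because of the filter, the tally and the camera p may overstate the lean toward rises, by an amount that was not measured.

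The counterpart hypothesis for the parental cells, a basal and squamous programme, found no such pattern. Because Krt14, Col7a1 and S100a7a stood among the largest falls, 43 other basal and squamous genes were listed in the same way, of which Krt5, Trp63, Perp and Itga2 are also in the lists fixed earlier. Of the 24 tested, 8 fell and 9 rose (the same adjusted over the list alone), and camera did not call the list (adjusted p = 0.574, and adjusted p = 0.836 with an estimated correlation). Among the rises, Trp63, Ly6d and Grhl3, with 0, 5 and 6 parental counts, were tested only through the spheres. These 3 could only rise, so here the filter leans the tally against the hypothesis. The test pointed down, while the median (0.09) and mean (0.88) log2 fold changes of the list were above 0. Without those 4 genes, 8 fell and 7 rose of 20 (adjusted p = 0.331). The list's genes lay above the other spheres in sphere replicate 1 by a median of 0.66 on the log2 scale. Without that library 9 fell and 9 rose of 24 (adjusted p = 0.247), with a median log2 fold change of -0.12. With each library left out in turn, the adjusted p was between 0.247 and 0.884, and between 0.289 and 0.96 with an estimated correlation. Serpinb5 fell from 22.6 ± 2.9 to 3.84 ± 2.4 CPM and Gjb3 from 38.5 ± 2.1 to 8.62 ± 0.80 CPM, whereas Sprr1a rose from 1.21 ± 0.14 to 38.6 ± 25 CPM and Trp63, with no parental count, was at least 76.9-fold higher.

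A further question is where the RNA of genes silent in the parental libraries came from. All 152 genes had counts in each sphere library, but the filter on low counts required that of any gene with no parental count. Of the 152, 119 reached a mean of 1 CPM in spheres. RNA of the tumour that Matrigel is made from would bring Lama1, its main laminin chain, which had 0 counts over the 3 sphere libraries. Normal lung tissue would bring Sftpc and Scgb1a1, which together had 0 counts there, beside 5369 for Sftpd. Failed estimates at overlapping genes would concentrate in genes that overlap another, but 15.1% of these genes do, against 19.8% of all tested genes. A change of state in the cultured cells, outgrowth of a small part of the line, and RNA from another mouse line or a mislabelled culture stay open. Cdkn2a, Kdm5d and Ddx3y had no count in any of the 6 libraries, and Xist was present in both groups (322 CPM in parental cells and 1020 CPM in spheres), values that another line could share by chance.

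Sphere replicate 1 differed from sphere replicates 2 and 3. After all 3 were thinned to the depth of replicate 1, r across genes was 0.973 and 0.972 with replicate 1 and 0.984 between the other 2, a gap of 0.011, so the lower depth of replicate 1 does not account for it. Its immediate early genes lay above the other spheres by a median of 1.21 on the log2 scale, against a 95th percentile of 0.10 in 10000 random lists matched on expression. Of the other 37 lists, 20 also lay above the 95th percentile of their own random lists, among them host defence (1.57), alveolar type 1 (0.95), RAS-ERK (0.92) and inflammatory genes (0.84), and 5 lay below the 5th. The test therefore did not single out early-response genes, and what set this library apart stays open, since the labels give no harvest time or batch and no other biological explanation was tested.

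The real grouping of the libraries called 7542 genes, and the highest of the other 9 ways to divide them into 3 and 3 called 0 with edgeR, where 28 to 87 genes had an unadjusted p under 0.05. With 10 splits in all, of which 1 gave as many genes, a share under 0.05 cannot be reached. Each of the other 9 also mixed parental and sphere libraries, so the difference between these widened the spread within its groups. Few calls could arise there, and no conclusion is drawn from the comparison. Longer transcripts were not broadly favoured: the Spearman rho of log2 fold change with transcript length was 0.083 across the 12656 genes, which argues against a length bias as the source of the wide change.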
